A study of Arabidopsis thaliana with 4 samples.

How the data were processed

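The series measured the DNA associated with FHY1 in Arabidopsis thaliana seedlings by ChIP-seq. The labels give 3 biological replicates of the ChIP and 1 input DNA sample from seedlings carrying 35S:GFP-FHY1 in the fhy1-1 background, etiolated, 4 days old and treated with far-red light for 3 h. The labels name an anti-GFP antibody, whereas the design text names an antibody against FHY1. The input was not analysed here, so no comparison with it was made. Samples were grouped by their titles, and no comparison between conditions was possible within the 1 condition.

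Reads were aligned with Bowtie to TAIR10, per the submitters' processing notes, which give no Bowtie version. The peak caller, its settings and the background it used are not given in the sources used here. The authors deposited 1 peak list per replicate and 1 list for the whole series. The replicate lists have no header, and the meaning of their columns was taken from the values and their layout, in which the length column equals end minus start plus 1, so that positions count from 1. Each deposited replicate list holds a whole-number tag count per peak, which the authors did not normalise as far as the values show. The authors' score per peak was read as a scaled negative logarithm of a p-value, from its layout. The authors' fold enrichment is a ratio per peak over a background that is not stated. The deposited false discovery rate is a percent per peak. The lowest deposited score was 50 in replicates 1 and 2 and 50.01 in replicate 3, and the highest false discovery rate was 4.88%, 4.96% and 4.96%, so the lists contain only peaks past the authors' thresholds. The authors' series list gives a peak height as its signal, a whole number of at least 40, in columns named for samples 1 to 3. Neither the scaling of this signal nor the way the series list was made is stated, and its samples were not matched to replicate numbers. Scores, folds and heights are the authors' own and were used to describe and rank peaks within a list.

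The depth of the libraries is unknown. The peaks of replicates 1, 2 and 3 held 4541953, 12651543 and 10390173 tags over 9.51, 22.4 and 19 Mb, with a median of 444, 360 and 451.5 tags per peak. These sums depend on how many peaks were called and are not depths.

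Coordinates are those of the peaks in TAIR10. Gene names, gene types and neighbours were taken from a RefSeq table of assembly TAIR10.1 with 37887 nuclear genes, of which 27432 are protein-coding, and none of its own coordinates is given. The match of the coordinates was checked by moving the shared regions. The share of midpoints inside genes was lowest without a shift on each of the 5 chromosomes, at 40.5% to 41.5%, and was 61.1% to 66.2% after shifts of 2000 bp. Strand, exons and UTRs were not used here. The windows around transcription starts that had been planned were therefore replaced by distances to either gene end, and promoter and UTR classes were not placed. No genome sequence was used here, so the planned motif test was not run.

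Replicate overlap was the share of peaks that overlapped a peak of another replicate by at least 1 bp. It was compared with 1000 random placements of the peaks within their chromosomes, with a one-sided permutation p and Benjamini-Hochberg adjustment over the 6 directed comparisons. Shared regions were the stretches covered by peaks of at least 2 of the 3 replicates, and all-3 stretches were covered by all of them. For genomic location, midpoints were put in the first class that held. The order was in a protein-coding gene, within 1000 bp of a protein-coding gene end, in another annotated gene or pseudogene, or farther away. Midpoints in non-coding genes or pseudogenes within 1000 bp of a protein-coding gene end therefore count in the flank class. The same random placement, with a two-sided permutation p, was used for location and for the overlap of non-coding genes. Intervals on shares of genes are 95% Wilson intervals and cover counting error only. A region was assigned to the gene that held its midpoint, or else to the nearest protein-coding gene within 1000 bp. The number of list members with a region was compared with all other protein-coding genes by Fisher's exact test, two-sided, adjusted over 28 tests with a threshold of 0.05. Genes that share a region are not independent in this test, and gene length was not matched in it. Score agreement was Spearman's rho over overlapping peaks with 100000 permutations.

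The gene lists, the kinds of test and the alternatives named below as fixed in advance were set before the data were examined. The assignment by gene ends, the location classes and the matching of families on symbols replaced the rules planned then. The 14 gene lists were phytochrome and far-red signalling, circadian clock and flowering time, photosynthesis, tetrapyrrole and chlorophyll synthesis, flavonoid and anthocyanin synthesis, auxin, gibberellin, brassinosteroid, ethylene, abscisic acid, cell wall and expansion, stress and defence, abundantly transcribed housekeeping genes, and floral organ identity and seed storage, the last 2 as controls. Of their 329 genes, 328 were in the annotation. The 14 families (ribosomal protein, transcription factor, kinase, cytochrome P450, chlorophyll a-b binding, SAUR, heat shock, histone, pentatricopeptide, F-box, disease resistance, TCP, bHLH and MYB) were found by their words in symbols and synonyms, since gene descriptions were not used here. They therefore hold only members named in that way. Families were also formed from the letters that open the symbols, after the data were seen, and the result of 1 such family is not reported here.

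The genes named were FHY1, FHL, PHYA and PHYB, the 20 genes whose all-3 stretches had the highest mean percentile of the authors' score within the 3 lists, up to 4 members of each gene list in the same order, and the top 10 regions of the series list by mean height. For members with a peak in 2 replicates, the absent one was counted as percentile 0. Other names are said to be chosen after their values were seen.

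Alternatives fixed in advance were all-3 stretches, leaving out each replicate, the upper 50% of each list by score, equal list lengths (the top 8423 peaks), the authors' series list, an overlap of 50% of the shorter peak (with 100 placements for the replicate overlap), and the genome outside 178 pericentromeric bins of 100 kb in which pseudogenes outnumbered protein-coding genes. Alternatives chosen after seeing the data were flanks of, and assignment within, 500 or 2000 bp of a gene end in place of promoter lengths, assignment of each gene with an end window (1000 bp outside to 200 bp inside) or flanks overlapped, placement at the same distance from a random gene end, peak summits, 10000 random lists matched on the gaps beside the genes, and a background of the 10363 genes with a symbol.

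The methods were tested on simulated data. Shared regions matched those of bedtools in all 10521 stretches of simulated lists, and in all 17470 of the replicate lists. With no effect, the overlap test gave a p of 0.05 or less in 2.5% of 40 runs, and with 5% of peaks planted on peaks of the other list it did so in 100% (a permutation test). In these runs both lists were placed at random within chromosomes, and lists that share a preference for gene ends were not simulated. The overlap and location runs used fewer placements than the tests on the data. With no list changed among the 27432 genes, each drawn independently, 6% of runs called any list. Dependence between genes that share a region was not simulated. Odds raised 4 times were called in 99% of runs for the phytochrome list, 81% for the clock, 91% for photosynthesis and 50% for tetrapyrrole synthesis, and odds raised 2 times in 40%, 13%, 18% and 1%. The location test reached 0.05 in 10% of 20 runs with no effect and in 100% with 5% of midpoints moved to gene flanks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1, were used.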

Results

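Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the DNA associated with FHY1 in Arabidopsis thaliana seedlings. FHY1 carries the far-red photoreceptor phyA into the nucleus, and the study asked which genes it associates with in far-red light. The seedlings expressed a GFP-FHY1 fusion from the constitutive 35S promoter in the fhy1-1 mutant. They were grown in darkness for 4 days and then given 3 h of far-red light. The labels give anti-GFP as the antibody and the design text gives anti-FHY1, so the antibody is left open here. There were 3 biological replicates of the ChIP and 1 input DNA sample, and the input was not analysed here. Replicate 1 had 8423 peaks with a median width of 957 bp, replicate 2 had 28170 with 689 bp, and replicate 3 had 19150 with 859 bp. The peaks covered 9.51 Mb, 22.4 Mb and 19 Mb of the 5 nuclear chromosomes in replicates 1, 2 and 3. They held 4541953, 12651543 and 10390173 tags, and the total depth of the libraries is unknown. The authors' fold enrichment had a median of 4.06 in replicate 1, 3.92 in replicate 2 and 4.16 in replicate 3. All comparisons are between regions or genes of 1 condition, since no second light treatment or genotype was analysed here.

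Most replicate 1 peaks lay on peaks of the other replicates, while the larger lists held many peaks of their own. Of the replicate 1 peaks, 81.7% overlapped a replicate 2 peak and 81.1% a replicate 3 peak by at least 1 bp. Replicate 3 peaks were found in replicate 2 at 72.4% and in replicate 1 at 36.9%. Replicate 2 peaks were found in replicate 3 at 52.2% and in replicate 1 at 26.9%. Peaks found in neither other list numbered 621 in replicate 1 (7.37%), 12288 in replicate 2 (43.6%) and 4332 in replicate 3 (22.6%). In a one-sided permutation test with 1000 random placements within chromosomes, chance overlap was 13.1% to 38.5%. The observed shares were 1.96 to 2.66 times chance in the 6 comparisons, each with an adjusted p of 0.001, the smallest that the placements can give. With the strongest 8423 peaks of each list, 50.2% to 56.3% overlapped, against 15% to 15.7% by chance, and the ratios rose to 3.34 to 3.59, whereas with peaks placed at the same distance from a random gene end they were 1.44 to 2.0.

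**Figure D1:**
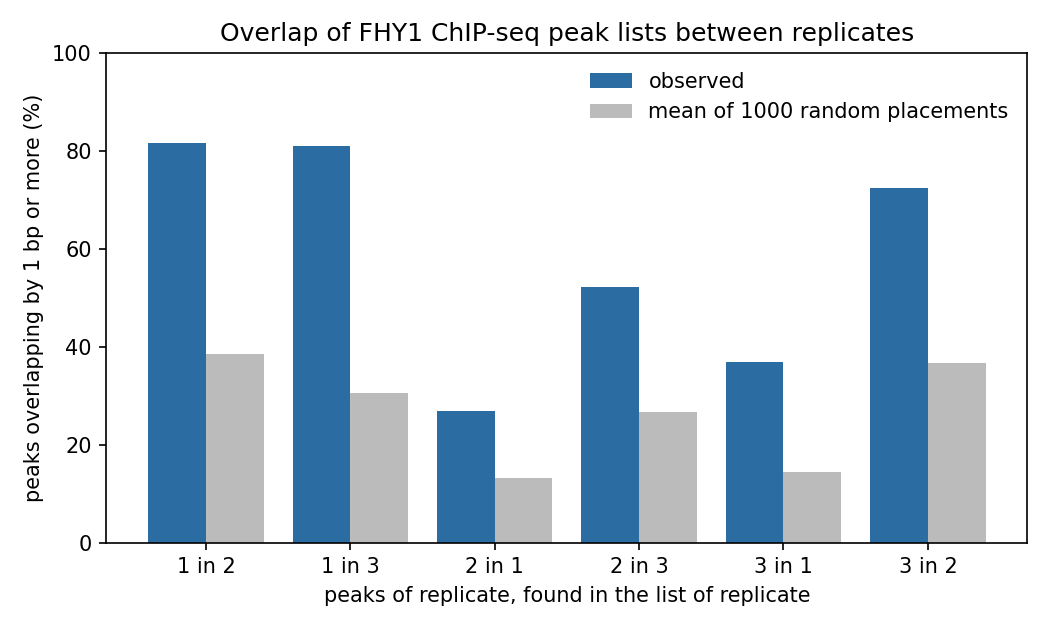
Share of the peaks of each replicate (in %) that overlap a peak of another replicate by 1 bp or more (blue), beside the mean of 1000 random placements within chromosomes (grey). The observed shares run from 26.9% to 81.7% and the chance shares from 13.1% to 38.5%.

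Regions covered by peaks of at least 2 of the 3 replicates, called shared regions, numbered 17470. They covered 13.9 Mb and had a median width of 723 bp. Peaks of all 3 replicates covered 6687 stretches, with a median width of 698 bp. Shared regions were assigned to 11460 of 27432 nuclear protein-coding genes (41.8%), and all-3 stretches to 5031 genes (18.3%). A gene was assigned if it held the midpoint of the region, or else was the nearest gene within 1000 bp. Without replicate 2 there were 7317 regions near 5716 genes, without replicate 3 there were 7838 near 5866 genes, and without replicate 1 there were 15695 near 10280 genes.

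Shared regions lay near the ends of protein-coding genes more often than by chance, and in gene interiors and pseudogenes less often. Midpoints fell outside protein-coding genes but within 1000 bp of the end of one for 7711 regions. This is 44.1%, against 20.4% ± 0.308 by chance (SD over 1000 random placements). A further 7143 midpoints (40.9%) lay in a gene body, against 54.2% ± 0.366 by chance. In the 250 bp on the outer side of a gene end lay 25.6% of all midpoints, and in the 250 bp on the inner side also 25.6%, against 7.82% and 11.7% by chance. Midpoints in other annotated genes, pseudogenes included, that lay farther than 1000 bp from a protein-coding gene end made up 1.01%, against 8.59% by chance. Outside pericentromeric bins these shares were 0.953% and 3.40%. The random placements took no account of whether reads could be aligned at a position. The differences in the location classes had an adjusted p of 0.002 each in a two-sided permutation test over 4 classes, the smallest it can give, and the 250 bp bins were not tested. The strand of the genes was not used here, so upstream and downstream ends, UTRs, exons and introns were not told apart. Positions in no annotated gene and farther than 1000 bp from a protein-coding gene end held 14% of midpoints, against 16.8% by chance. Outside pericentromeric bins the direction turned, with 13.7% against 11.9%. With a flank of 500 bp this class was at 0.982 times chance, with an adjusted p of 0.174.

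**Figure D2:**
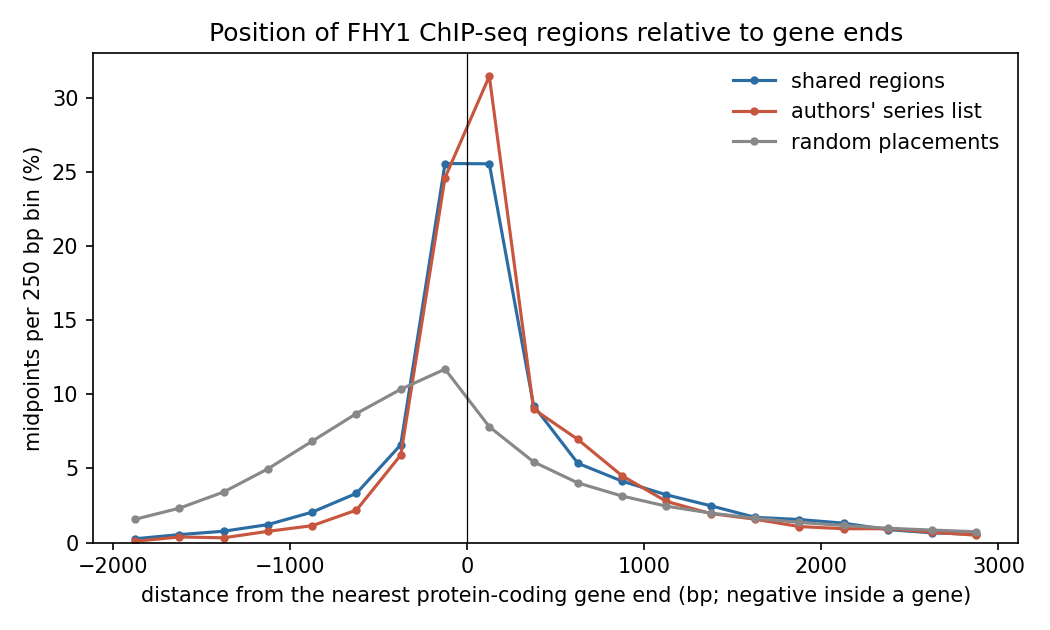
Midpoints of the shared regions (blue), of the authors' series list (red) and of random placements (grey), as % per 250 bp bin of the distance in bp to the nearest protein-coding gene end, with negative distances inside genes. The bins on both sides of the gene end each hold 25.6% of the shared regions, against 11.7% inside and 7.82% outside by chance.

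Genes of phytochrome and far-red signalling had shared regions more often than other genes. Of the 53 genes in this list, 39 had a region (73.6%), against 41.7% of other protein-coding genes, and 25 of the 53 had an all-3 stretch (47.2%). PHYB, which encodes the main photoreceptor for red light, had a region on chromosome 2 from 8137877 to 8140581, with its midpoint outside the gene. The fold enrichments there were 7.19, 5.83 and 6.61 in replicates 1, 2 and 3. The bHLH genes PIF5 and PIF6, whose family acts directly below phytochromes, had folds of 6.42, 4.18 and 4.77 and of 6.20, 6.32 and 5.96. The homeodomain gene HAT2 had 5.94, 3.84 and 3.81. No shared region was assigned to FHY1, its homologue FHL or PHYA. Peaks lay within 1000 bp of FHY1 in each replicate, with highest folds of 8.74, 4.73 and 3.82, and near FHL with 5.45, 5.39 and 8.21, but for no shared region was either of them the gene that held the midpoint or lay nearest to it. Near PHYA there was 1 peak in replicate 1 at fold 3.5 and 1 in replicate 2 at 3.55, and none in replicate 3. The list had 14 members without a region, and HY5, CRY1 and SPA1, chosen here after their values were seen, were among them. The odds ratio of the list was 3.89 (Fisher's exact test, two-sided, adjusted p = 3.68e-05 over 28 lists and families). Against genes that have a symbol it was 2.77 (adjusted p = 0.00732, Fisher's exact test).

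Of the other 13 lists fixed in advance, 7 had regions more often than other genes. Photosynthesis genes had a region in 32 of 40 cases (odds ratio 5.59), among them RBCS1A, for the small subunit of Rubisco, with folds of 3.89, 4.05 and 8.0, and LHCB1.5, for an antenna protein, with 5.39, 5.21 and 5.17. Circadian clock and flowering genes had one in 23 of 29 (5.35), among them the clock genes LHY, with 7.92, 6.94 and 5.19, and GI, with 5.94, 5.55 and 5.82. Stress and defence genes had one in 16 of 20 (5.58), including MYC2, a regulator of jasmonate responses, with 5.51, 6.17 and 8.32, and the cold-response genes CBF2 and CBF3. Auxin genes had one in 26 of 36 (3.63), including IAA2 with 8.19, 8.13 and 6.07, the auxin receptor gene TIR1 and ARF19. Brassinosteroid genes had one in 14 of 18 (4.88), including BZR1, BEE1, BES1 and the synthesis gene DWF4 with 6.26, 7.26 and 4.18. Cell wall genes also had one in 14 of 18, including XTH24, XTH33, EXPA1 and the cellulose synthase gene CESA1. Gibberellin genes had one in 12 of 16 (4.18), including GA2OX6, RGL3, the receptor gene GID1A and RGA, a repressor of gibberellin responses. The adjusted p values of these lists, by Fisher's exact test, were 1.48e-05 for photosynthesis, 0.000544 for the clock, 0.0035 for stress, 0.00141 for auxin, 0.00911 for brassinosteroid and for cell wall, and 0.0269 for gibberellin. Against genes with a symbol, adjusted p stayed at 0.05 or less for photosynthesis (0.0025), the clock (0.0173), stress (0.049) and auxin (0.049), and rose to 0.0958 for brassinosteroid and cell wall and to 0.165 for gibberellin, whose call was also lost against random lists matched on the gaps beside the genes (0.0611). Calls were lost without replicate 1 for gibberellin (odds ratio 2.78, adjusted p of 0.106) and cell wall (2.62, 0.0933), without replicate 2 for cell wall (3.04, 0.0711), and without replicate 3 for auxin (1.84, 0.136), while the odds ratio was 2.79 for photosynthesis without replicate 1, and 8.61 for photosynthesis and 11.1 for stress without replicate 3.

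The remaining lists did not pass the test. Tetrapyrrole and chlorophyll synthesis had a region in 13 of 22 genes, among them GUN4, CHLM, HEME1 and CHLI2. Flavonoid synthesis had one in 11 of 19, among them CHS, for the first enzyme of the pathway, with folds of 12.37, 4.1 and 6.08, and PAL2, C4H and 4CL1. Abscisic acid genes had one in 11 of 18, among them ABI5, PYL4, HAB1 and NCED3, and ethylene genes in 9 of 12, among them EBF1, EBF2, EIL1 and EIN2, whose folds were 4.47, 10.01 and 4.65. The adjusted p values were 0.181, 0.196, 0.182 and 0.0706 in that order (Fisher's exact test). Of the control lists, abundantly transcribed housekeeping genes had a region in 7 of 9, including GAPC1, ACT7, ACT2 and TUB2, with an odds ratio of 4.88 (Fisher's exact test, adjusted p = 0.0706). Floral organ and seed storage genes had one in 6 of 18, among them SEP1, AP3, LFY and CRA1 (odds ratio 0.697, Fisher's exact test, adjusted p = 0.634). In all-3 stretches flavonoid (adjusted p of 0.0145) and housekeeping genes (0.0291) passed the test and auxin genes did not (0.0542).

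**Figure D3:**
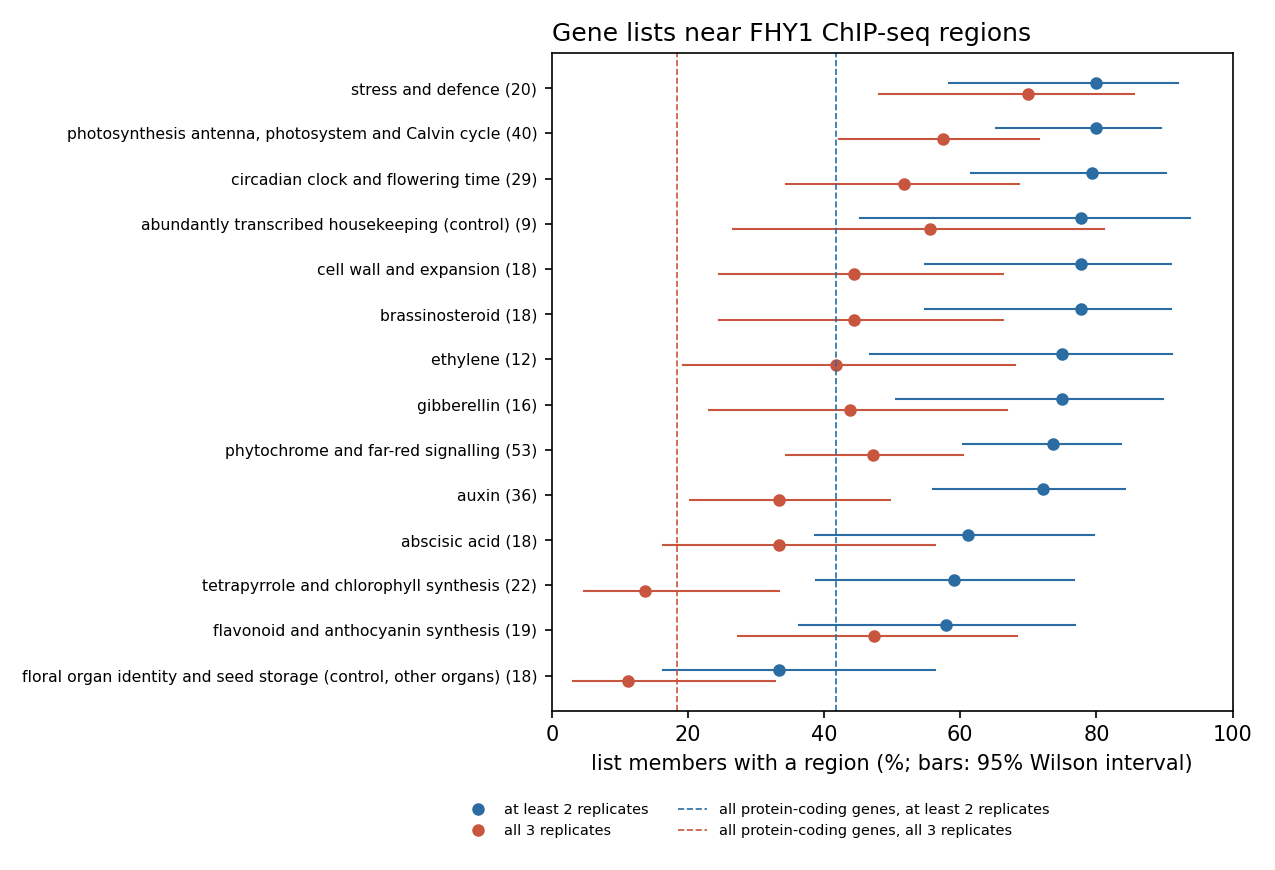
Share of the members of each gene list (in %, list size in brackets) that have a region shared by at least 2 replicates (blue) or by all 3 (red), with 95% Wilson intervals; dashed lines give the share of all protein-coding genes, 41.8% and 18.3%. Phytochrome and far-red signalling stands at 73.6% in regions of at least 2 replicates, and floral organ identity and seed storage at 33.3%.

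Of the gene families recognised by their symbols, kinases, transcription factors and F-box genes had regions more often than other genes. Regions were assigned to 309 of 583 kinase genes (53.0%, odds ratio 1.59), 65 of 110 genes named as transcription factors (59.1%, 2.02) and 20 of 31 F-box genes (64.5%, 2.54). Adjusted p by Fisher's exact test was 1.09e-06, 0.00141 and 0.0416. Against genes with a symbol none of these calls was kept, with adjusted p of 0.100, 0.148 and 0.277 (Fisher's exact test), and F-box genes also lost theirs against random lists matched on the gaps beside the genes (0.0728). Cytochrome P450 genes had a region in 82 of 232 cases (35.3%) and SAUR genes in 24 of 80 (30%), with adjusted p of 0.0814 and 0.0706. Against genes with a symbol both were lower, with odds ratios of 0.534 (adjusted p of 0.000115) and 0.228 (0.049), the SAUR value resting on 3 of the 16 members that have a symbol other than their locus code. Ribosomal protein genes (36 of 67), chlorophyll a-b binding protein genes (9 of 13), heat shock genes (30 of 53), histone genes (11 of 18), pentatricopeptide genes (53 of 115), disease resistance genes (3 of 13), TCP genes (9 of 12), bHLH genes (17 of 31) and MYB genes (67 of 147) did not pass the test, with adjusted p from 0.0706 to 0.370. Leaving out 1 replicate ended the call of transcription factors (without replicate 2, adjusted p of 0.0779) and F-box genes (without replicate 1, 0.106). It added calls for TCP genes (without replicate 1, 0.0403), heat shock genes (without replicate 2, 0.0169, and without replicate 3, 0.0405) and histone genes (without replicate 3, 0.019).

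Of the 20 genes whose all-3 stretches ranked highest by the authors' score, the highest was TCP9, a TCP transcription factor gene. Its stretch on chromosome 2 from 18819102 to 18821240 had its midpoint outside the gene and folds of 9.70, 5.14 and 4.66. PHYB was also among them, with its all-3 stretch from 8137924 to 8140076. ARR9, a response regulator gene of cytokinin signalling, had a stretch on chromosome 3 from 21107884 to 21109102 with folds of 8.05, 5.97 and 8.15. SPL12, a SQUAMOSA promoter-binding-like gene, had one on chromosome 3 from 22169620 to 22170452 with 6.80, 9.35 and 7.43. BZR1, a transcription factor gene of brassinosteroid signalling, had one on chromosome 1 from 28183196 to 28186060 with 4.03, 5.72 and 5.06. The homeobox gene ANL2, the peptide gene RALF23, the senescence-associated gene SAG20, iPGAM2 for a phosphoglycerate mutase and CAX2 for a vacuolar cation exchanger were also among the 20, as were AT3G13310, AT3G15200, AT2G45300, AT4G01245, AT3G59940, AT3G61690, AT5G13100, AT5G46910, AT1G25550 and AT1G80290. AT3G13310 and CAX2 are neighbours, and the same replicate 1 and replicate 2 peaks gave both entries. In 16 of the 20 the midpoint lay outside the gene, and the lowest mean percentile of the score over the 3 lists was 98.1. The ranking took no account of the deposited false discovery rate. Among the 20 highest folds of replicates 2 and 3 this rate tended to rise with the score. In replicate 2 it was 0.94% at a score of 607.1 and 3.98% at 1751.85, and TCP9 had a score of 1738.49 there. A high rank by score is therefore not a low false discovery rate.

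The authors' series list held 3419 regions, each with a peak height in 3 samples that were not matched to replicate numbers. Every one overlapped all 3 replicate lists. Of the 6687 all-3 stretches, 3014 (45.1%) overlapped the series list, which for this and for location and genes was taken as the stretches common to its 3 samples. Peaks in it had median folds of 4.29, 4.85 and 4.94 in replicates 1, 2 and 3, against 4.03, 4.34 and 4.55 for peaks of all-3 stretches outside it. By mean height the highest regions lay at AT1G79620, on chromosome 1 from 29957151 to 29957661 (469 ± 22.6, SD, n = 3), at the peptide gene RALFL34, on chromosome 5 from 26767411 to 26767971 (455 ± 137), and at AT1G06550 (442 ± 39.6). SQE3, for a squalene epoxidase (413 ± 58.0), AT1G72275 (379 ± 124), AT1G78410 (375 ± 112), HMG1, for an HMG-CoA reductase (358 ± 131), and AGL77, a MADS-box gene (355 ± 67.3), were also in the top 10. The other 2 regions, on chromosome 1, had no protein-coding gene within 1000 bp of their midpoints. The series list was assigned to 2633 genes. Of its midpoints, 51.6% lay outside protein-coding genes within 1000 bp of the end of one. By chance it was 20.4%, with an adjusted p of 0.002 by the permutation test. Phytochrome genes had a region in 16 of 53 cases (odds ratio 4.09, Fisher's exact test, adjusted p = 0.000599) and stress genes in 9 of 20 (7.73, with the same adjusted p). Photosynthesis (0.048), cell wall (0.0335), flavonoid (0.0335), housekeeping (0.0335) and heat shock genes (0.0114) also passed, while the clock list (0.286), auxin (0.267), gibberellin (0.286), brassinosteroid (0.206), kinases (0.206), transcription factors (0.267) and F-box genes (0.0777) did not.

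Genes for small structural RNAs were overlapped by shared regions more often than by chance, and pseudogenes less often. This overlap was planned as a check on the peak lists, at loci prone to unspecific ChIP signal. Since no input was analysed here, such signal cannot be told apart from association with FHY1. Regions overlapped 294 of 625 tRNA genes, against 75.1 ± 9.59 by chance (SD over 1000 random placements), which is 3.92 times as many. They overlapped 33 of 82 snRNA genes (2.98 times chance), 85 of 287 snoRNA genes (2.37 times) and 1074 of 3480 lncRNA genes (1.77 times). Annotated pseudogenes, which in this annotation include transposable element genes, were overlapped in 156 of 4843 cases, 0.0973 times the 1603 by chance. For miRNA genes 42 of 326 were overlapped, against 43.1 by chance (adjusted p of 0.957), and for rRNA genes 0 of 4. The other differences had an adjusted p of 0.0028 in a two-sided permutation test. When regions were moved to the same distance from a random gene end, the ratios were 2.48 for tRNA genes and 0.470 for pseudogenes with the same adjusted p. In the series list they were 6.59 for tRNA genes, 7.34 for snRNA genes, 0.0567 for pseudogenes and 1.41 for snoRNA genes, the last with an adjusted p of 0.834 by permutation.

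Peaks with a high score in 1 replicate tended to have a high score in another, to a limited degree. Spearman's rho of the authors' score over overlapping peaks was 0.207 for replicates 1 and 2 (6748 pairs of peaks), 0.303 for replicates 1 and 3 (6663 pairs) and 0.382 for replicates 2 and 3 (13271 pairs). In the series list the heights had rho of 0.673, 0.564 and 0.563 between the 3 samples. Each had a p of 1e-05 in a permutation test, the smallest that 100000 permutations can give. These correlations are across peaks, which are not independent replicates. With the fold enrichment in place of the score, rho was lower, at 0.143 for replicates 1 and 2, 0.249 for 1 and 3 and 0.239 for 2 and 3. The heights are another measure on fewer regions, so their rho cannot be set against that of the score.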

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

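Flanks of or assignment within 500 or 2000 bp, end-window and flank assignment, placement by distance from a gene end, peak summits, gap-matched lists and the background of genes with a symbol were chosen only after the data were seen. The 6 replicate overlaps stayed above chance, and the excess near gene ends and the deficit in gene bodies kept their direction and call, under each alternative run for them, with ratios of 1.89 to 2.62 and 0.660 to 0.831 for the last 2. The number of shared regions was 17470 and fell to 6687 in all 3 replicates, 8518 with the upper 50% of each list, 7967 with equal list lengths and 3419 in the authors' series list, and was 7317 to 15695 with 1 replicate left out. By construction, all-3 stretches need more replicates, and the other settings start from fewer peaks or regions. The 11 lists and families called higher became 7 in the series list, 5 against genes with a symbol, 16 with equal list lengths, and 14 each in all 3 replicates, with the upper 50% of each list and within 2000 bp. Calls were gained for ethylene with equal list lengths (adjusted p of 0.0491) and within 2000 bp (0.00311), for abscisic acid with the upper 50% (0.024) and equal list lengths (0.0187), and for housekeeping genes with equal list lengths (0.0491). Among families they were gained for heat shock genes in all 3 replicates (0.0225), with the upper 50% (0.0283), equal list lengths (0.0228), end windows (0.00379) and flanks (0.00574), for histone genes in all 3 replicates (0.0225) and with equal list lengths (0.0187), for TCP genes with the upper 50% (0.021), equal list lengths (0.0491) and within 2000 bp (0.0151), for bHLH genes within 2000 bp (odds ratio 3.17, 0.0086) and with end windows (2.89, 0.0417), for MYB genes within 2000 bp (1.55, 0.019) and for ribosomal protein genes within 500 bp (0.0388). Cytochrome P450 genes were lower with equal list lengths (0.0228), end windows (0.0049) and flanks (0.0129), and SAUR genes with end windows (0.00831) and flanks (0.00574), all by Fisher's exact test, and SAUR genes also against gap-matched lists (0.0443, permutation). With an overlap of 50% of the shorter peak, ethylene genes were higher (0.0413) and SAUR genes lower (0.0476, Fisher's exact test). Phytochrome, photosynthesis and stress genes kept their call in each of the 14 alternatives, and the clock list lost it only in the series list (0.286). Gibberellin, brassinosteroid, cell wall and F-box genes also lost theirs with end-window assignment (0.123, 0.0858, 0.0858 and 0.0858) and flanks (0.165, 0.0992, 0.0992 and 0.107), gibberellin with equal list lengths (0.0954) and F-box genes within 2000 bp (0.0522).

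Some directions turned, uncalled unless stated. Tetrapyrrole genes had odds ratios of 0.703 in all 3 replicates, 0.792 with equal list lengths and 0 in the series list. Floral and seed storage genes had 1.39 with end windows and 1.33 with flanks. Chlorophyll a-b binding genes had 0.785 in the series list. Pentatricopeptide genes had 0.995 in all 3 replicates and 0.762 against genes with a symbol. For bHLH genes it was 0.659 in all 3 replicates, 0.992 with the upper 50% of each list and 0.544 to 1.57 with 1 replicate left out. For MYB genes it was 0.992 within 500 bp, 0.800 against genes with a symbol and 0.974 to 1.32 with 1 replicate left out. The ratio for miRNA genes was 1.07 with placement by distance from a gene end and 1.01 with an overlap of 50% of the shorter peak. Positions in no annotated gene and farther than 1000 bp from protein-coding genes turned to 1.15 times chance outside pericentromeric bins. There the difference was called (adjusted p of 0.002, permutation test). For these turns the cause was not tested. The motif alternatives and those for windows around transcription starts, region midpoints in them and upstream gaps were not run. No paired analysis was possible because only 1 group has replicates. Depth is unknown, so no gene can be called unbound.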

Other observations

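The test of symbol families, the backgrounds of gap-matched lists and of genes with a symbol, and the tests of the strongest peaks of replicate 1 and of its tags in them were chosen only after the data were seen. Genes were grouped by the letters that open their symbols, which gave 97 families of at least 15 members among the 10363 genes with a symbol. Several families had shared regions less often than other genes with a symbol. Neither gene length nor gap length was matched for these families, and assignment by the midpoint of a region may depend on both. Among the cysteine-rich peptide genes named LCR, 13 of 81 had a region (16.0%, against 50.5% of the others), and among the related SCRL genes 2 of 27 (7.41%). Genes whose symbols open with CYP, as those of cytochrome P450 genes do, had one in 81 of 229 (35.4%). UMAMIT transporter genes had one in 10 of 44 (22.7%) and RALFL peptide genes in 6 of 32 (18.8%). Genes whose symbols open with ERF, as those of many AP2/ERF transcription factor genes do, had one in 19 of 23 (82.6%, odds ratio 4.72, 95% interval 1.60 to 13.9). Adjusted p over the 97 families, by Fisher's exact test, was 1.6e-08 for LCR, 8.68e-05 for SCRL, 0.00012 for CYP, 0.00437 for UMAMIT, 0.00483 for RALFL and 0.0357 for ERF. In all-3 stretches LCR (1.64e-06), SCRL (0.0208) and CYP (0.000573) were still lower, while UMAMIT (0.523), RALFL (0.421) and ERF (0.125) did not pass the test. There BBX genes, which encode B-box proteins and some of which are in the phytochrome list, were higher (13 of 20, 65%, odds ratio 6.18, adjusted p of 0.00256), and SCPL genes were lower (2 of 49, 4.08%, 0.0124), neither of which passed in regions of at least 2 replicates (0.385 and 0.183).

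Of 28 lists and families, 11 were near shared regions more often than other genes. Longer gaps beside the listed genes are argued against as the whole cause, since 81.8% of the 11 calls were kept against random lists matched on gap length, but gibberellin genes (12 observed, 7.05 by chance, adjusted p of 0.0611 by permutation) and F-box genes (20 observed, 13.8 by chance, 0.0728) were not, and ribosomal protein genes gained one (36 observed, 25.7 by chance, 0.0398). A candidate explanation for part of it is that genes with a symbol lie near regions more often (50.2%, against 36.6% without), since 45.5% of the calls were kept against that background. Odds ratios fell there from 4.88 (95% interval 1.61 to 14.8) to 3.47 (1.14 to 10.6) for brassinosteroid and for cell wall genes, from 4.18 (1.35 to 13) to 2.98 (0.959 to 9.23) for gibberellin, from 2.02 (1.38 to 2.955) to 1.46 (0.986 to 2.15) for transcription factors, from 1.59 (1.35 to 1.87) to 1.21 (1.01 to 1.44) for kinases and from 2.54 (1.21 to 5.30) to 1.87 (0.834 to 4.21) for F-box genes, and these calls ended as the estimates fell, with unchanged members for the first 3 lists, whereas the last 3 families also lost members without a symbol, so that the background was not the only change for them. Signal that follows abundant transcription stays open, since the median odds ratio of the called lists was 4.18 and lay between that of ribosomal protein genes (1.62) and that of housekeeping genes (4.88), and no input or transcript level was analysed here. No biological explanation was tested, as the design has 1 condition.

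Replicate 1 had fewer peaks than replicates 2 and 3. Whether weak peaks missed in replicate 1 are part of this stays open. Of the top 10% of replicate 2 peaks by score, 64.6% were found in replicate 1 (16.4% by chance). Of the bottom 10% it was 8.98% (11.2% by chance), a difference of 55.6 percentage points. Recovery in the longer replicate 3 list also rose, from 1.07 times chance for the bottom 10% to 2.74 times for the top 10%. The rise is therefore not particular to replicate 1. It cannot tell weak peaks missed there from weak replicate 2 peaks that do not recur. That a few loci took most of the tags in its peaks is argued against, since the 33 replicate 1 peaks over fold 12 held 2.07% of those tags. Tags outside the called peaks are unknown, so whether a few loci took most of the library's reads stays open. Whether replicate 1 was sequenced less deeply was not tested, because total depth is unknown. No biological explanation was tested, since all 3 replicates belong to 1 group.

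Most of the strongest peaks of replicate 1 were not in the other lists. Its 20 highest folds were 18.69 to 86.01, the highest on chromosome 3 from 14202685 to 14202943, and 17 of these peaks overlapped no peak of another replicate, whereas the 20 highest folds were 9.6 to 11.49 in replicate 2 and 9.57 to 11.26 in replicate 3, and 12 of 20 overlapped both other lists in each. Reads from multi-copy ribosomal DNA may account for part of them, since 11 of the 20 lay within 5000 bp of an annotated rRNA gene, against 0 in replicate 2 and 1 in replicate 3. This stays open because the positions had been seen before the test and because the other peaks, most of them on chromosome 2, lay near no annotated rRNA gene. Absence from a list is also not absence of signal, as no list holds a false discovery rate above 4.96%. Among the 20 highest folds of replicates 2 and 3 this deposited rate tended to rise with the score. It was 0.94% at 607.1 and 3.98% at 1751.85 in replicate 2. In replicate 3 it was 0.56% at 479.4 and 3.76% at 1214.55. Whether strong peaks of these 2 lists were lost at that limit was not tested. No biological explanation was tested.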
